A study of Mus musculus with 6 samples.

How the data were processed

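RNA was measured in 6 libraries of microglia from the brains of aged mice, 3 wild type (WT) and 3 Cop1 knockout (COP1KO). Per the labels' protocols, total RNA was extracted with an RNeasy kit with on-column DNase digestion, 0.5 µg went into a TruSeq RNA v2 library for polyA RNA, and a HiSeq4000 was used to produce 50 bp single-end reads, with 30M planned per library. This kit does not mark strand. Age at collection, sex, litter, batch and the way microglia were isolated are not given in the sources used here, nor is the part of Cop1 that was deleted. Replicate numbers were assigned here only to tell libraries apart.

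Per the file headers, the count column as deposited holds the raw number of reads that aligned uniquely to each gene model, with no normalization. Per the file headers, the RPKM column as deposited was made by the authors from reads per kilobase and depth, and was further adjusted by the authors with a size factor per library whose method is not given in the sources used here. Per the submitters' processing notes, reads were aligned with GSNAP to GRCm38; the versions and the gene annotation release are not given. The count column was used for every result, and the RPKM column only to check that its library scaling was the same for all genes of a library. Counting unique alignments loses reads from genes with near-identical copies, so values of histone genes, the Ifi200 family, H2-DMb1 and H2-DMb2, and of Gapdh and ribosomal protein genes, are uncertain.

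Each library had 52636 gene identifiers, of which 52403 matched a gene in the GENCODE M21 annotation and 233 did not; the latter held at most 0.0689% of reads in a library. Coordinates are GRCm38. Total counts ranged from 11.1M (WT_1) to 27.2M (WT_2). No library was left out and no 2 libraries were duplicates: within groups, log2 CPM correlated at 0.950 to 0.978 across genes, which are not independent replicates, and the lowest chi-square per degree of freedom was 8.12, between WT_1 and WT_3.

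COP1KO was compared with WT in R 4.3.3 with edgeR 4.0.16: TMM factors (0.912 to 1.13), the filterByExpr filter by group, which kept 16278 genes and removed 36358, and the quasi-likelihood test with robust dispersion. The common biological coefficient of variation was 30.7%. All adjusted p for genes are Benjamini-Hochberg values from this edgeR test unless another tool is named, and a gene is called when its adjusted p is under 0.05. Standard errors of log2 fold changes were derived from the fold change and the test statistic. "Adjusted over the list alone" means Benjamini-Hochberg adjustment of the edgeR p over the tested members of 1 list. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. For genes with 1 to 3 reads over the WT group, a ratio with its exact binomial 95% counting interval is given, which covers counting error only. Cop1 also had an exact two-sided permutation test, where 0.1 is the smallest p possible.

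Before the data were examined, 34 gene lists were fixed: components and substrates of the COP1 ligase, C/EBP-linked myeloid genes, ERK and ETS feedback genes, p53 targets, homeostatic and disease-associated microglial genes, proinflammatory and NF-kB genes, chemokines, complement, type I interferon response, MHC class II, MHC class I, Fc and phagocytic receptors, NADPH oxidase, lipid handling, lysosome, glycolysis and hypoxia, cell cycle, immediate early genes, mitochondrially encoded and sex-linked genes, and markers of border macrophages, monocytes, neutrophils, T and NK cells, B cells, dendritic cells, neurons, astrocytes, oligodendrocyte lineage, endothelium, mural cells and fibroblasts, choroid plexus and red blood cells. Some genes stand in more than 1 list. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and with fry, which asks whether a list moves on balance 1 way without comparing it with other genes. Lists needed at least 3 tested members.

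The genes named in the text were set by a rule fixed before the data were examined. It takes Cop1; the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 CPM and groups that do not overlap, passing over gene models without a regular symbol (1 and 2 were passed over) and sex-linked genes; the 5 smallest p; Cebpa, Cebpb, Cebpd, Jun, Ets1, Etv5 and Trib1; and from each list up to 2 called rises and 2 called falls, or the member with the smallest p where none was called. This gave 70 genes, of which 1 is not reported here. Other called list members are named as members, and other genes are said to have been chosen after their values were seen.

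Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile factors or library size alone in the same fit, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom with and without sample quality weights, no robust dispersion, 1 surrogate variable from sva 3.50.0, minimum fold changes of 1.2 and 1.5, and leaving out each library. Chosen after seeing the data were a term for the sex-linked pattern, the fit without COP1KO_3 and WT_2, and camera with DESeq2 size factors, upper quartile factors or 1 surrogate variable. The pipeline was tested on simulated data with the same depths, where 50 genes each were changed by 1.5, 2, 4 and 8-fold: 0%, 22%, 62% and 90% were recovered, and 6 of 93 calls were false (6.45%). Only genes above a minimum expected count were changed, and counts were drawn independently for each gene and library. No sex-linked pattern or outlying library was simulated, so these rates may not hold for the real libraries. Figures were drawn with matplotlib 3.10.9.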

Results

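Bulk RNA sequencing of microglia, the resident macrophages of the brain, was used to measure gene expression in aged mice after loss of Cop1. Cop1 encodes an E3 ubiquitin ligase that marks transcription factors such as JUN, ETS and C/EBP proteins for degradation. The 6 libraries fell into 2 groups, 3 wild type (WT) and 3 Cop1 knockout (COP1KO), and the microglia were collected more than 1.5 years after the deletion. Each library is named here by its group and a number that only tells the libraries of a group apart. The deposited counts (M, 1e6 reads) summed to 11.1M reads in WT_1, 27.2M in WT_2, 18.9M in WT_3, 23.5M in COP1KO_1, 23.2M in COP1KO_2 and 22.1M in COP1KO_3. WT_1 was thus the shallowest library, and its low counts carry the largest counting error. The labels do not say whether the libraries of a group came from separate animals. The female-specific transcript Xist and the Y-linked gene Ddx3y, described below, differed between libraries within each group. The libraries of a group therefore did not all come from the same animals, while those alike in these genes may have. The p-values measure only the spread between these libraries, which includes this difference and may be technical in part.

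The targeted gene was examined first, as a check of the labels. Cop1 (ENSMUSG00000040782, GRCm38 chromosome 1, 159232320 to 159347640, plus strand, protein coding) stood at 6.93 ± 1.04 CPM in WT and 4.90 ± 0.905 CPM in COP1KO (mean ± SD, n = 3; CPM, depth-normalised read counts with TMM scaling). The WT libraries gave 8.13, 6.22 and 6.43 CPM and the COP1KO libraries 3.96, 5.0 and 5.76 CPM, from 85 to 154 reads per library. Every COP1KO library therefore lay below every WT library, at a mean of 70.8% of the WT level. The difference did not pass the test across all genes (log2 fold change -0.49, SE 0.27, edgeR adjusted p = 0.390). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 can reach. The sources used here do not say which part of the gene was deleted, and reads from outside the deleted part check nothing, so these counts neither establish nor contradict the labels.

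The single comparison in the design, COP1KO against WT, asks how microglia differ long after Cop1 was removed. Apoe, the gene of the lipid carrier apolipoprotein E, rose from 1974 ± 1477 CPM in WT to 44289 ± 3100 CPM in COP1KO (SD, n = 3). Of 32 interferon response genes 10 were called, all higher. Only 1 was called without WT_1, WT_3, COP1KO_1 or COP1KO_3, 7 without WT_2 and 25 without COP1KO_2. Of 30 genes of the resting microglial state 4 fell, Crybb1, Upk1b, Sall1 and Tmem100, and 26 were not called. The immune receptor genes Pilra, Cxcr2 and Clec7a rose as well. Of 16278 genes tested, 453 were called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 307 higher and 146 lower in COP1KO. Of the called genes 410 were protein coding. Among the genes called higher, 268 differed by more than 2-fold and 155 by more than 4-fold, against 97 and 16 of those called lower. For all 453 called genes the 3 COP1KO libraries lay on one side of the 3 WT libraries, which held for 22.6% of all tested genes, where chance gives 10%. Scaling by library size alone moved the median log2 fold change of all tested genes to -0.15 and the split of calls to 293 higher and 240 lower, or 55.0% higher in place of 67.8%. Without WT_1 88 genes were called, without WT_2 1829, without WT_3 119, without COP1KO_1 189, without COP1KO_2 412 (324 higher, 88 lower) and without COP1KO_3 184.

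The largest rises included genes that were almost silent in WT. Jaml, a junctional adhesion molecule of leukocytes (ENSMUSG00000048534, chromosome 9, 45079183 to 45108534), had 1 read in the 3 WT libraries together and 3023 in the 3 COP1KO libraries, a depth-corrected ratio of 2697 with a 95% counting interval of 484 to 106544. It reached 55.2, 32.7 and 51.7 CPM in the COP1KO libraries. Ifitm1, an interferon-induced membrane protein gene (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), rose from 0.0670 ± 0.0616 to 58.5 ± 17.2 CPM (log2 fold change 9.62, SE 0.50, edgeR adjusted p = 0.000179). Cxcr2, a chemokine receptor best known from neutrophils (ENSMUSG00000026180, chromosome 1, 74153989 to 74161246), rose from 0.0539 ± 0.0933 to 50.9 ± 18.3 CPM (log2 fold change 9.43, SE 0.61, adjusted p = 0.000577). All 4 of its WT reads were in WT_2. Without WT_2 its log2 fold change was 12.98, against 8.84 to 9.65 without any other 1 library. Further down the ranking, log2 fold changes were 6.90 (SE 0.81) for Saa3, an acute phase protein gene, 6.69 (SE 0.85) for Hpse, which encodes heparanase, 6.05 (SE 1.06) for Ifi205, 5.80 (SE 0.75) for Tarm1, 5.78 (SE 0.56) for Apoc1 and 5.69 (SE 0.60) for the histone gene Hist1h1d. Iqcn had 2 reads in WT and 793 in COP1KO, a ratio of 354 with a counting interval of 97.6 to 2926. Most of its signal was in COP1KO_3, at 30.4 CPM against 3.02 and 4.09 CPM in the others. The smallest p-value belonged to Pilra, an inhibitory immunoglobulin-like receptor gene (ENSMUSG00000046245, chromosome 5, 137821952 to 137836281), which rose from 28.7 ± 3.37 to 461 ± 40.6 CPM (log2 fold change 4.0, SE 0.18, adjusted p = 8.89e-05). Dna2, a helicase and nuclease gene, rose from 7.71 ± 0.905 to 64.5 ± 8.63 CPM (log2 fold change 3.07, SE 0.17, adjusted p = 0.000278). Pilra shares 15.2% of its exon bases with Zcwpw1 on the opposite strand and Jaml 12.8% with Gm10684, and the kit does not mark strand, so reads there cannot be assigned to one of the pair; over all libraries Zcwpw1 had 4004 reads and Gm10684 13, against 31924 for Pilra and 3024 for Jaml. The calls of Iqcn and Saa3 were lost without WT_1, WT_2 or WT_3 (7.74 to 10.95 and 6.66 to 7.20), that of Ifi205 without WT_1, WT_3, COP1KO_1 or COP1KO_3 (5.47 to 5.83), and those of Hpse and Tarm1 without WT_1 (6.30 and 5.72). Without WT_2 the log2 fold changes of Hpse and Tarm1 were larger, at 8.61 and 7.34. For Ifi205 (9.56), Iqcn (10.95) and Cxcr2 (12.98) no WT read was left without WT_2, so the size of those changes was not measured.

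The falls were smaller. Col6a3, which encodes a collagen VI chain (ENSMUSG00000048126, chromosome 1, 90765923 to 90843971), went from 72.4 ± 9.26 CPM in WT to 14.7 ± 1.99 CPM in COP1KO (log2 fold change -2.30, SE 0.17, edgeR adjusted p = 0.000857). Mfap4, an extracellular matrix gene, had the lowest log2 fold change among the named genes, -3.30 (SE 0.49), at 4.13 ± 2.0 CPM in WT and 0.410 ± 0.113 CPM in COP1KO. Next came Inmt at -3.01 (SE 0.58), the olfactory receptor gene Olfr111 at -2.98 (SE 0.59), the prostaglandin E receptor gene Ptger3 at -2.68 (SE 0.49), Myo18b at -2.48 (SE 0.33) and Map3k19 at -2.31 (SE 0.45). Gimap9, a GTPase of the immunity-associated family, fell from 26.1 ± 5.07 to 5.54 ± 1.62 CPM (log2 fold change -2.23, SE 0.27). Hlf, a transcription factor with a daily rhythm in many tissues, fell from 21 ± 6.03 to 4.71 ± 0.873 CPM (log2 fold change -2.15, SE 0.27). The calls of Mfap4, Inmt, Olfr111, Ptger3 and Map3k19 were each lost without WT_1, COP1KO_1 or COP1KO_3, with log2 fold changes from -3.49 to -2.31; those of Inmt, Olfr111, Ptger3 and Map3k19 were also lost without WT_3 (-3.12 to -2.28), those of Inmt and Olfr111 without COP1KO_2 (-2.69 and -2.82), and that of Myo18b without WT_1 (-2.36). Mfap4 shares 4.63% of its exon bases with Mapk7 on the opposite strand, which had 7174 reads against 244 for Mfap4.

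**Figure D1:**
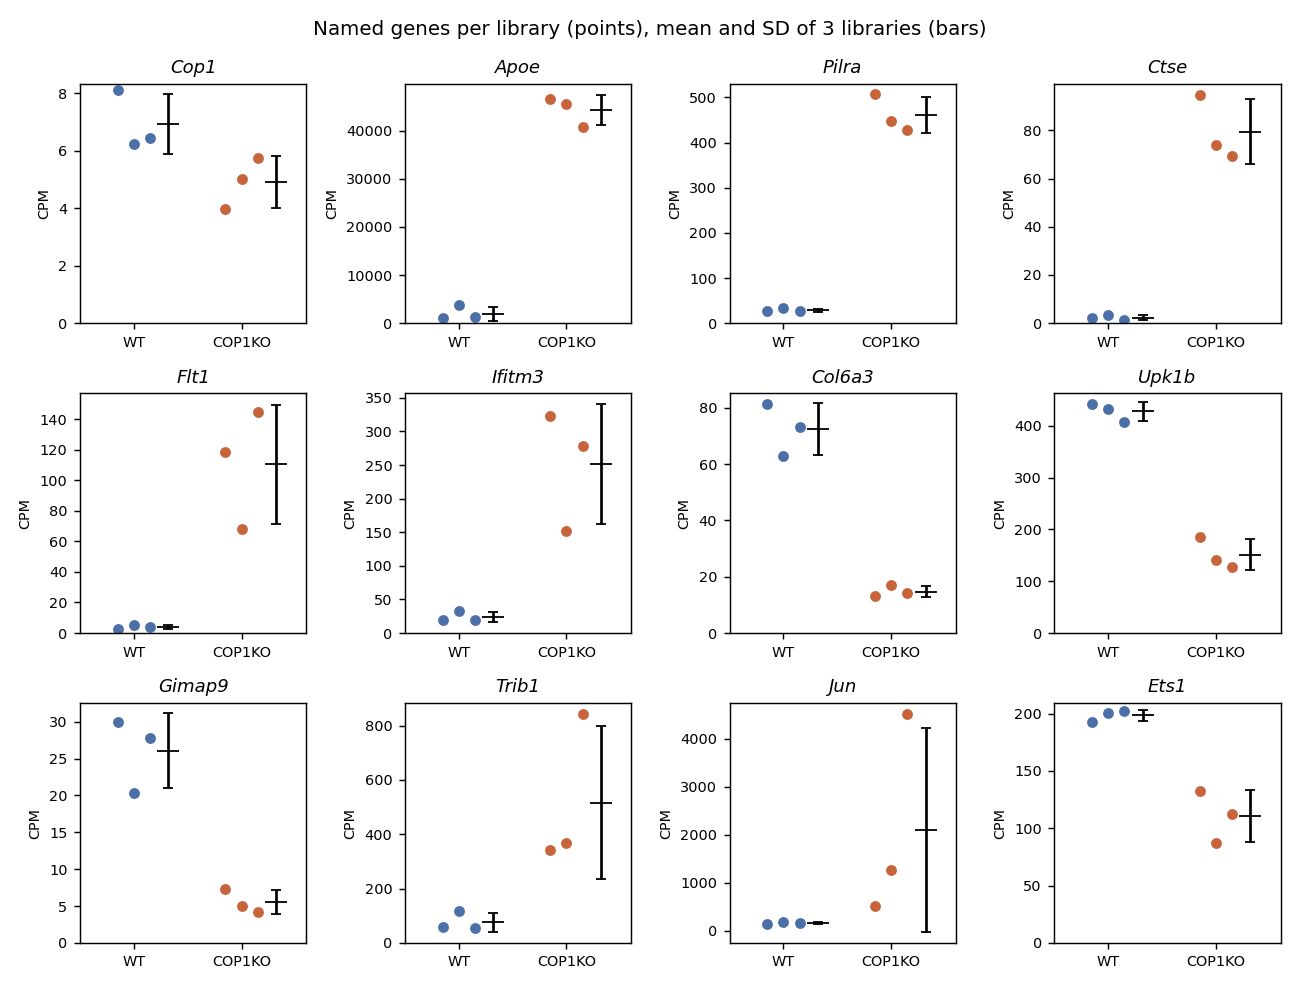
Each panel plots 1 gene in CPM on a linear axis for 3 WT and 3 COP1KO libraries (points, in replicate order), with the group mean and SD beside them. Apoe lay between 1047 and 3678 CPM in WT and between 40753 and 46537 CPM in COP1KO, and the spread of Jun within COP1KO came mostly from COP1KO_3, at 4512 CPM.

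Of the 54 named genes that were called, 17 stayed called under every one of 18 alternative settings that gave them a value. They included Jaml, Ifitm1, Cxcr2, Apoc1, Apoe, Hist1h1d, Pilra, Dna2, Ctse, Flt1, Ifitm3 and Nceh1 among the rises, and Col6a3, Gimap9, Hlf and Upk1b among the falls. Several measured differences between libraries did not follow genotype. The female-specific transcript Xist was at 56.8 CPM in WT_2, 193 CPM in COP1KO_1 and 271 CPM in COP1KO_3 and had no read in the other libraries, where the Y-linked gene Ddx3y was at 118 CPM (WT_1), 104 CPM (WT_3) and 104 CPM (COP1KO_2). Both patterns thus occurred in each group. With this pattern as a term, chosen after seeing the data, 766 genes were called, 494 higher and 272 lower.

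Among the components and substrates of the COP1 ligase, 2 of 19 tested genes were called higher, 1 lower and 16 were not called by edgeR (4 higher and 3 lower when adjusted over the list alone). DESeq2 called 4 higher and 3 lower, limma-voom 2 and 1, and limma-voom with quality weights 6 and 3. EdgeR called none without WT_1 or WT_3, 4 higher and 2 lower without WT_2, and 3, 2 and 2 higher without COP1KO_1, COP1KO_2 and COP1KO_3. Trib1, an adaptor that brings C/EBP proteins to COP1, rose from 76.2 ± 34.5 to 516 ± 282 CPM (log2 fold change 2.76, SE 0.44, edgeR adjusted p = 0.0169). Jun, a subunit of the AP-1 transcription factor, rose from 164 ± 26.1 to 2100 ± 2121 CPM (log2 fold change 3.67, SE 0.73, adjusted p = 0.0447). Its COP1KO values were 527, 1261 and 4512 CPM. Without COP1KO_3 the log2 fold change was 2.45 and still called, and without WT_1, WT_2 or WT_3 the call was lost, at 3.55, 3.79 and 3.68. The Trib1 call was lost without WT_1 or WT_3, at 2.58 and 2.57. Ets1 went the other way, from 198 ± 4.74 to 111 ± 22.6 CPM (log2 fold change -0.84, SE 0.17, adjusted p = 0.0464), and Etv5, at a log2 fold change of -0.85 (SE 0.22, adjusted p = 0.0951), was not called. The Ets1 call was lost without WT_1, WT_3, COP1KO_1, COP1KO_2 or COP1KO_3, with log2 fold changes from -0.99 to -0.72. Transcripts of the C/EBP family did not pass the test: the log2 fold change was -0.26 (SE 0.19, adjusted p = 0.526) for Cebpa, 0.86 (SE 0.25, adjusted p = 0.121) for Cebpb and -0.08 (SE 0.20, adjusted p = 0.879) for Cebpd. Cebpb was called without WT_2, at 1.15, and Cebpd turned positive without WT_2 (0.10) or COP1KO_1 (0.07). Cebpb and Cebpd share 20.7% and 15% of their exon bases with Tmem189 and Spidr on the opposite strand. Loss of a ubiquitin ligase acts on protein, which was not measured here. The list as a whole did not shift 1 way against other genes (camera adjusted p = 0.757, and adjusted p = 0.902 with an estimated correlation). Its median log2 fold change was -0.01 (0.15 without WT_2) while its mean was 0.50. Camera asks only for such a net shift, and members of this list moved both ways. Of the 19 members 11 had an unadjusted edgeR p under 0.05, against 2753 of all 16278 genes tested. Fry for changes in either direction gave an unadjusted p = 0.00583. Other lists had smaller p in that fry test, among them B cell markers (7.39e-05) and endothelial markers (0.000146). Of 32 interferon response genes 27 had an unadjusted edgeR p under 0.05. Neither value thus sets the COP1 list apart from other lists.

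Among genes linked to C/EBP factors in myeloid cells, 6 of 22 tested were called higher by edgeR and none lower (12 higher when adjusted over the list alone), with a median log2 fold change of 2.21. DESeq2 called 11 higher, limma-voom 1 and limma-voom with quality weights 13. EdgeR called none without WT_1 or WT_3, 2 without COP1KO_3, 6 without COP1KO_1, 7 without COP1KO_2 and 10 without WT_2, where the median was 4.06. Besides Saa3, the called members were S100a9, S100a8, Lcn2, Chil3 and Csf3r, of which Chil3 also stands in the monocyte list and the other 4 in the neutrophil list, so these calls cannot be counted apart from those of blood cell markers. S100a9, an alarmin of neutrophils and monocytes, had 1 read in WT and 181 in COP1KO, a ratio of 161 with a counting interval of 28.6 to 6412. The S100a9 call was lost without WT_1, WT_3 or COP1KO_3 (6.66, 8.85 and 5.87). Its WT read was in WT_3, so the 8.85 rests on no WT read. The calls of Saa3 were lost without any 1 WT library (6.66 to 7.20) and those of Chil3 without WT_1, WT_3, COP1KO_1 or COP1KO_3 (4.73 to 5.14). The list was called with camera's preset correlation (adjusted p = 4.41e-09), and its adjusted p = 0.651 with an estimated correlation. Of 11 ERK and ETS feedback genes none was called, although 5 had an unadjusted p under 0.05 (2 higher and 1 lower when adjusted over the list alone; edgeR). DESeq2 called 1 of these lower, limma-voom none, and limma-voom with sample quality weights 2 higher and 1 lower. EdgeR called 1 lower with library size alone, with 1 surrogate variable or with the sex-linked term, and 1 higher without WT_2, COP1KO_2 or COP1KO_3. The smallest p in that list belonged to Etv5, and camera gave adjusted p = 0.659. None of 18 p53 target genes was called (edgeR), 6 had an unadjusted p under 0.05, and the smallest p was that of Perp (log2 fold change -1.40, SE 0.38, adjusted p = 0.104). DESeq2 called 1 p53 target higher and 1 lower, limma-voom none, and limma-voom with quality weights 1 lower; Perp was called without WT_2, at -1.59, and camera gave adjusted p = 0.814.

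Of 30 homeostatic genes, those of the resting microglial state, 4 were called lower by edgeR, none higher and 26 were not called (8 lower when adjusted over the list alone), with a median log2 fold change of -0.36. DESeq2 called 9 lower, limma-voom 4 and limma-voom with quality weights 8, and edgeR 1 without WT_1, 6 without WT_2, 3 without COP1KO_1 and 2 without WT_3, COP1KO_2 or COP1KO_3. Crybb1 fell from 216 ± 37.3 to 63.0 ± 19.3 CPM (log2 fold change -1.78, SE 0.25, edgeR adjusted p = 0.0116) and Upk1b from 428 ± 18.2 to 151 ± 30.2 CPM (log2 fold change -1.50, SE 0.18, adjusted p = 0.00650). The other called members were Sall1, a transcription factor of microglial identity, at -0.96 (SE 0.19), and Tmem100 at -0.72 (SE 0.14). The commonly used markers P2ry12 (log2 fold change -0.89, adjusted p = 0.182) and Tmem119 (-0.08, adjusted p = 0.912), chosen after their values were seen, were not called. The list's adjusted p was 1.30e-05 with camera's preset correlation, 0.651 with an estimated correlation and 0.202 with fry. The Crybb1 call was lost without WT_1, at -1.87. Without WT_2 the list was not called (median -0.19, camera adjusted p = 0.0793); its genes summed to 130745 CPM in WT_2 against 83186 and 81841 CPM in WT_1 and WT_3 and 67335 to 88001 CPM in COP1KO.

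Among genes of the disease-associated microglial state, 7 of 35 tested rose, 1 fell and 27 were not called by edgeR (19 higher and 2 lower when adjusted over the list alone), with a median log2 fold change of 0.94. DESeq2 called 15 higher and 2 lower, limma-voom 6 and 1, and limma-voom with quality weights 20 and 2. EdgeR called 19 higher and 2 lower without WT_2, 11 higher without COP1KO_2, 3 without WT_1 and 4 without WT_3, COP1KO_1 or COP1KO_3. Apoe, which encodes the lipid carrier apolipoprotein E (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), rose from 1974 ± 1477 to 44289 ± 3100 CPM (log2 fold change 4.49, SE 0.55, edgeR adjusted p = 0.00695). The log2 fold change of Apoe was 5.31 without WT_2 and 4.18 to 4.55 without any other 1 library. Its mean share of all counts was 4.22% ± 0.362 in COP1KO and 0.196% ± 0.121 in WT (SD, n = 3). The lowest COP1KO share was 3.83% in COP1KO_3 (exact 95% binomial interval 3.83% to 3.84%) and the highest WT share 0.335% in WT_2 (0.333% to 0.337%), intervals that cover counting error only. Axl, a receptor tyrosine kinase for apoptotic cells, rose from 90.4 ± 68.1 to 739 ± 201 CPM (log2 fold change 3.03, SE 0.51, adjusted p = 0.0208), a call lost without WT_1, WT_3, COP1KO_1 or COP1KO_3 (2.75, 2.74, 2.93 and 2.89). Clec7a, Fth1, Cd52, Cd22 and Itgax also rose. Serpine2 fell from 953 ± 240 to 359 ± 104 CPM (log2 fold change -1.41, SE 0.28, adjusted p = 0.0395), a call lost without any 1 library except WT_2 (-1.61 to -1.22). Spp1, chosen after its values were seen, was set apart by library and not by group, at 99.0 CPM in WT_2, 164 CPM in COP1KO_1 and 109 CPM in COP1KO_3 against 30.9 CPM in WT_1, 28.9 CPM in WT_3 and 19.4 CPM in COP1KO_2. The list's adjusted p was 2.67e-08 with camera's preset correlation, and adjusted p = 0.651 with an estimated correlation. Summed over the list, WT_2 stood at 47631 CPM, above WT_1 at 27220 CPM and WT_3 at 28150 CPM and below the COP1KO libraries at 86986 to 101141 CPM.

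Of 25 lipid handling genes, 2 rose, 1 fell and 22 were not called by edgeR (7 higher and 1 lower when adjusted over the list alone). DESeq2 called 6 higher, limma-voom 2 and limma-voom with quality weights 8, each with 1 lower. EdgeR called 8 higher and 1 lower without WT_2 and 4 higher without COP1KO_2. Besides Apoe, Nceh1, a cholesterol ester hydrolase gene, rose from 30.4 ± 6.94 to 122 ± 23.8 CPM (log2 fold change 2.0, SE 0.22, edgeR adjusted p = 0.00459), while Mylip, which encodes the ubiquitin ligase that degrades the LDL receptor, fell from 350 ± 24.3 to 181 ± 9.11 CPM (log2 fold change -0.95, SE 0.14, adjusted p = 0.0139). The Mylip call was lost without any 1 library except WT_2 (-0.99 to -0.93). The adjusted p for the list was 0.00041 with the preset correlation, and adjusted p = 0.667 with an estimated correlation. Of 28 lysosomal genes 1 was called, the protease gene Ctse, at 2.36 ± 1.06 CPM in WT and 79.4 ± 13.5 CPM in COP1KO (log2 fold change 5.05, SE 0.33, adjusted p = 0.000577). It was also the only call when adjusted over the list alone, and limma-voom called 1 as well, DESeq2 6 and limma-voom with quality weights 19, all higher. Without WT_2 edgeR called 18 higher, with a median of 0.81. With TMM scaling all 28 members had a fitted change above 0, and with library size alone 24 did; the median was 0.45 (camera adjusted p = 4.51e-07, and adjusted p = 0.651 with an estimated correlation). The lysosomal genes summed to 50390, 89162 and 51292 CPM in WT_1, WT_2 and WT_3 and to 98922, 75694 and 85946 CPM in the COP1KO libraries, so WT_2 lay among the COP1KO libraries.

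Of 32 interferon response genes tested, 10 were called higher by edgeR and none lower (26 higher when adjusted over the list alone), with a median log2 fold change of 1.61. DESeq2 called 22 higher, limma-voom 1, limma-voom with quality weights 18 and edgeR with 1 surrogate variable 3. EdgeR called 1 without WT_1, WT_3, COP1KO_1 or COP1KO_3, 7 without WT_2 and 25 without COP1KO_2. Ifitm3, an antiviral membrane protein gene next to Ifitm1, rose from 23.4 ± 7.77 to 251 ± 89.2 CPM (log2 fold change 3.42, SE 0.34, edgeR adjusted p = 0.00370). Rsad2, which encodes viperin, rose from 4.69 ± 0.420 to 22.8 ± 12.9 CPM (log2 fold change 2.28, SE 0.47, adjusted p = 0.0457). The Rsad2 call was lost without COP1KO_1, COP1KO_3, WT_1, WT_2 or WT_3 (1.98, 2.07, 2.31, 2.32 and 2.20). Irf7, Usp18, Oasl2, Zbp1, Ifit1, Sp100, Cmpk2 and Bst2 were the other called members. The list had the smallest camera p of all lists (adjusted p = 5.24e-12 with the preset correlation), against 0.651 with an estimated correlation and 0.202 with fry. Summed CPM over the list were 1050, 1221 and 1098 in WT and 3302, 1625 and 3544 in COP1KO, with COP1KO_2 the lowest of the COP1KO libraries.

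Among antigen presentation genes, 2 of 10 MHC class II genes were called higher (3 when adjusted over the list alone): H2-DMb2, at 10.8 ± 0.707 and 47.2 ± 20.8 CPM (log2 fold change 2.13, SE 0.30, edgeR adjusted p = 0.0111), and H2-DMa, at 251 ± 69.4 and 608 ± 47.9 CPM (log2 fold change 1.27, SE 0.22, adjusted p = 0.0239). The H2-DMb2 call was lost without WT_1 or WT_3 (2.15 and 2.16), and the H2-DMa call without any 1 library except WT_2 (1.14 to 1.33). H2-DMa shares 10.4% of its exon bases with Brd2 on the opposite strand, and H2-DMb2 has a close copy, H2-DMb1, whose reads can be lost when only unique alignments are counted. The class II list had a camera adjusted p of 0.00327, and adjusted p = 0.651 with an estimated correlation. Nlrc5, a transactivator of MHC class I genes, was the only 1 of 17 class I genes called over all genes tested (log2 fold change 1.85, SE 0.39, adjusted p = 0.0481), while 15 of the 17 were higher when adjusted over the list alone. DESeq2 called 3 class II and 10 class I genes higher, limma-voom 2 and 0, and limma-voom with quality weights 3 and 13. EdgeR called 7 class I genes without WT_2, 6 without COP1KO_2 and none without any other 1 library, and of the class II genes none without WT_1 or WT_3, 3 without WT_2 and 1 without any 1 COP1KO library. The Nlrc5 call was lost in 11 of the 18 alternative settings, among them the fits without any 1 library except COP1KO_2 (1.28 to 1.99). In COP1KO_2 the class I genes summed to 5883 CPM, against 9534 and 13395 CPM in COP1KO_1 and COP1KO_3 and 5390 CPM in WT_2. The class I list had a camera adjusted p of 1.35e-07, and adjusted p = 0.651 with an estimated correlation.

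Proinflammatory, chemokine and complement genes were uneven. Of 27 proinflammatory and NF-kB genes, 3 rose (Saa3, Ikbke and Gpr84) and none fell (12 higher and 1 lower when adjusted over the list alone); DESeq2 called 9 higher and 1 lower, limma-voom 1 higher, and limma-voom with quality weights 10 higher and 1 lower. EdgeR called none without WT_1 or WT_3, 6 higher and 2 lower without WT_2, and 2, 7 and 3 higher without COP1KO_1, COP1KO_2 and COP1KO_3. Ikbke, a kinase upstream of interferon genes, stood at 0.465 ± 0.269 CPM in WT and 5.92 ± 3.50 CPM in COP1KO (log2 fold change 3.64, SE 0.63, edgeR adjusted p = 0.0242). Of 16 chemokine genes, Cxcl9 (log2 fold change 3.52, SE 0.68) and Ccl12 (3.20, SE 0.51) rose and Ccl9 fell from 117 ± 5.78 to 40.2 ± 14.5 CPM (log2 fold change -1.54, SE 0.27). Adjusted over the list alone, 12 chemokines were higher and 2 lower; DESeq2 called 10 and 2, limma-voom 1 and 1, and limma-voom with quality weights 6 and 2. EdgeR called no chemokine without WT_1 or WT_3, 2 higher and 2 lower without WT_2, 9 higher and 1 lower without COP1KO_2, and 2 higher without COP1KO_1 or COP1KO_3. The calls of Ikbke, Cxcl9 and Ccl9 were lost without WT_1, WT_3, COP1KO_1 or COP1KO_3 (3.08 to 3.73, 3.01 to 3.58 and -1.72 to -1.51), and those of Saa3 and Ccl12 without any 1 WT library (6.66 to 7.20 and 3.12 to 3.27). COP1KO_3 stood apart in both lists, with chemokines summing to 7776 CPM there against 1504 CPM in COP1KO_1, 1009 CPM in COP1KO_2 and 590 to 728 CPM in WT. The adjusted p was 8.78e-06 for the NF-kB list and 0.00041 for the chemokines with camera's preset correlation, and adjusted p = 0.651 for both with an estimated correlation. Of 17 complement genes only C3, the central complement component, was called, at 6.50 ± 5.36 CPM in WT and 153 ± 99.4 CPM in COP1KO (log2 fold change 4.54, SE 0.83, adjusted p = 0.0451), and the list was not called (camera adjusted p = 0.202, and adjusted p = 0.881 with an estimated correlation). Without WT_2 it was called higher (median 1.16, adjusted p = 0.00577), and without COP1KO_2 as well (0.10, adjusted p = 0.0187). C3 was also the only call when adjusted over the list alone; DESeq2 called 3 complement genes higher, limma-voom 1, limma-voom with quality weights 4 higher and 1 lower, and edgeR 3 higher without WT_2. The C3 call was lost without COP1KO_1, COP1KO_3, WT_1, WT_2 or WT_3, with log2 fold changes from 3.96 to 5.50.

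Of 21 Fc and phagocytic receptor genes, 4 rose and none fell by edgeR (7 higher when adjusted over the list alone, and 7 with DESeq2, 3 with limma-voom and 10 with quality weights): Cd300lf (log2 fold change 4.04, SE 0.52), Axl, Clec7a and Fcgr2b, which encodes the inhibitory Fc receptor. Without WT_2 8 were called, without COP1KO_2 6, without COP1KO_3 3, without COP1KO_1 2 and without WT_1 or WT_3 1. The Cd300lf call was lost without WT_1 or WT_3 (3.84 and 4.05), and the Axl call without WT_1, WT_3, COP1KO_1 or COP1KO_3 (2.74 to 2.93). The camera adjusted p was 0.000241 with the preset correlation, and adjusted p = 0.651 with an estimated correlation. Cybb, the catalytic subunit gene of the phagocyte oxidase, rose from 54.3 ± 49.8 to 728 ± 282 CPM (log2 fold change 3.74, SE 0.68, edgeR adjusted p = 0.0351) and was the only 1 of 7 NADPH oxidase genes called, also when adjusted over the list alone. Limma-voom with quality weights called 2 of the 7, as did edgeR without WT_2. That list was not called (camera adjusted p = 0.0582, and adjusted p = 0.715 with an estimated correlation), but was called higher without WT_2 (median 0.30, adjusted p = 0.0148), without COP1KO_3 (0.21, adjusted p = 0.0360) and with upper quartile factors (0.17, adjusted p = 0.0488). The WT spread of Cybb came from WT_2, at 112 CPM against 29.3 and 21.9 CPM in WT_1 and WT_3. The Cybb call was lost without WT_1, WT_3, COP1KO_1 or COP1KO_3 (3.36 to 3.68).

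**Figure D2:**
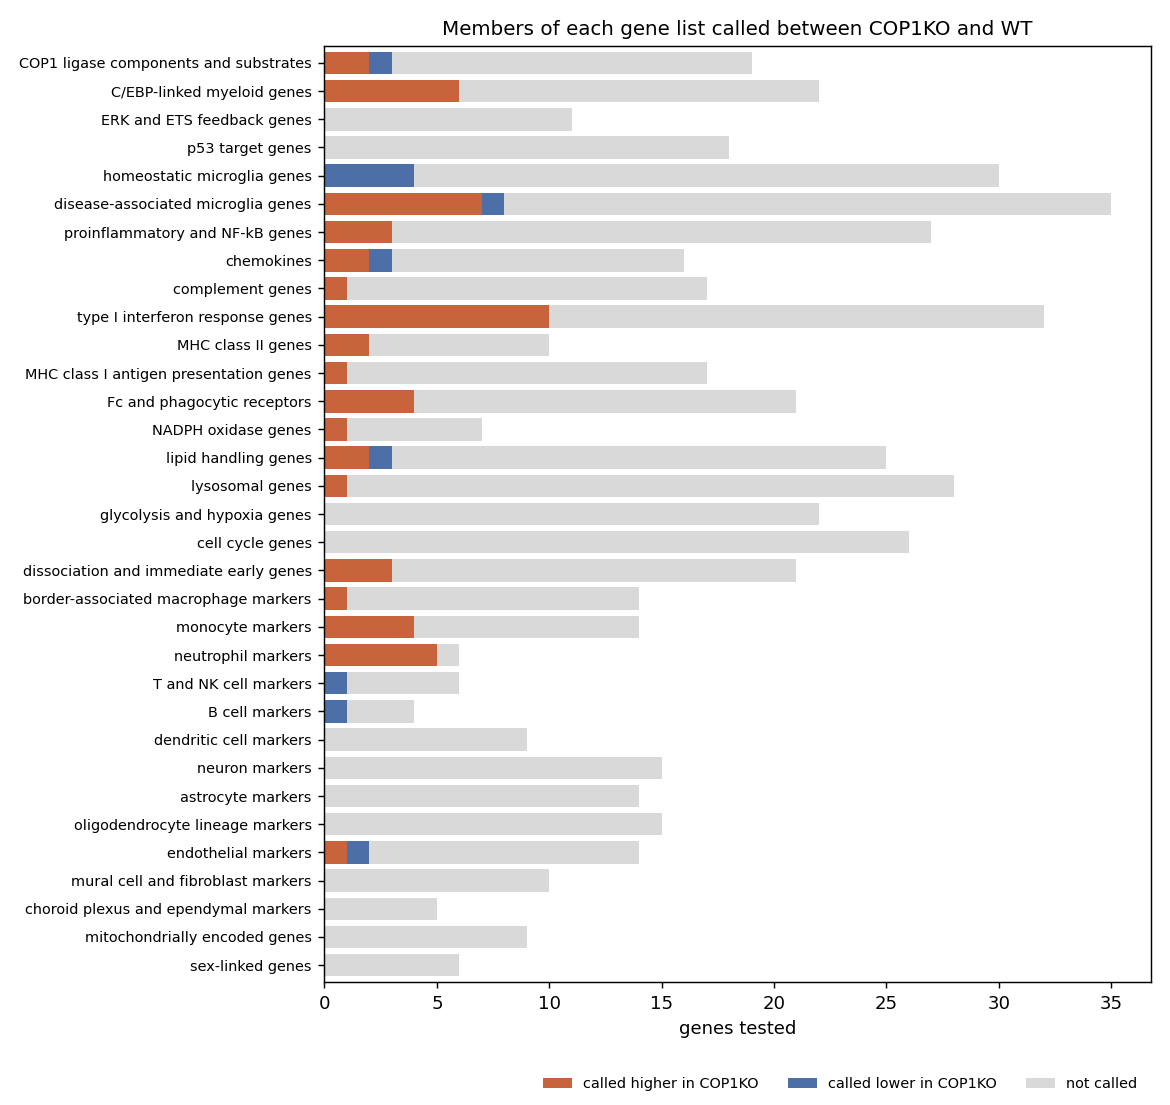
Horizontal bars give the number of tested members of each gene list that were called higher, called lower or not called in COP1KO against WT (edgeR, adjusted over all genes tested). With all libraries and edgeR, 10 of 32 interferon genes and 5 of 6 tested neutrophil markers (15 listed) were called. The interferon count was 1 without WT_1, WT_3, COP1KO_1 or COP1KO_3. The neutrophil count was 1 of 9 without WT_1 or WT_3 and 2 of 6 without COP1KO_3.

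Immediate early genes, which respond within minutes to stimulation or to tissue dissociation, were tested next. Of 21, 3 were called higher by edgeR and none lower (13 higher when adjusted over the list alone, and 7 with DESeq2, 3 with limma-voom and 8 with quality weights), and all 21 had a fitted change above 0, with a median of 3.51. No member was called without WT_1, WT_2 or WT_3, and 7, 8 and 7 were without COP1KO_1, COP1KO_2 and COP1KO_3. Ier2 stood at 18.8 ± 8.33 CPM in WT and 534 ± 522 CPM in COP1KO (log2 fold change 4.83, SE 0.84, edgeR adjusted p = 0.0351), and the other called members were Jun and Zfp36. COP1KO_3 stood far above the rest. Fos was at 2577 CPM in COP1KO_3, 106 CPM in COP1KO_1, 139 CPM in COP1KO_2 and 6.38 to 9.94 CPM in WT. Without COP1KO_3 the median was 1.06, and Ier2 was still called, at 3.67. Its call was lost without WT_1, WT_2 or WT_3, at 4.65, 5.26 and 4.64. The list had a camera adjusted p of 1.35e-07 with the preset correlation, and adjusted p = 0.651 with an estimated correlation.

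Markers of other cells were examined because a microglial preparation can hold them. Of 15 listed neutrophil markers, 6 had enough counts to be tested with all libraries. Of these, 5 were called higher by edgeR (also when adjusted over the list alone, with DESeq2 and with quality weights, against 2 with limma-voom): Cxcr2, S100a9, S100a8, Lcn2 and Csf3r. The count was 1 of 9 without WT_1 or WT_3, 2 of 6 without COP1KO_3, 4 of 6 without COP1KO_2, 6 of 9 without WT_2 and 7 of 9 without COP1KO_1. Csf3r, a receptor that WT microglia also carried at 575 CPM, stood at 1198 CPM in COP1KO. S100a8 and S100a9 had 1 WT read each. They passed the count filter through their COP1KO reads alone and could hardly be called lower, so the share of markers called higher is in part set by the filter. The neutrophil list was the only list called by fry (adjusted p = 0.0132). Camera gave it an adjusted p of 1.35e-07, and adjusted p = 0.651 with an estimated correlation. Of 14 monocyte markers, 4 rose and none fell (5 when adjusted over the list alone, and 5 with DESeq2, 2 with limma-voom and 5 with quality weights). Itgal, an integrin chain, went from 5.50 ± 6.37 to 238 ± 59.0 CPM (log2 fold change 5.39, SE 0.84, edgeR adjusted p = 0.0258) and Chil3 from 0.0673 ± 0.117 to 3.45 ± 2.01 CPM (log2 fold change 5.31, SE 1.02, adjusted p = 0.0357), with Fn1 and Ms4a4c also called. Without WT_1 or WT_3 1 was called, without COP1KO_1 or COP1KO_3 3, without COP1KO_2 4 and without WT_2 5. The Itgal call was lost without WT_1 or WT_3 (5.03 and 4.93), the Chil3 call without WT_1, WT_3, COP1KO_1 or COP1KO_3 (4.73 to 5.14), and the S100a9 call without WT_1, WT_3 or COP1KO_3 (6.66, 8.85 and 5.87). Without WT_2 the log2 fold change of Itgal was larger, at 7.05. All 5 WT reads of Chil3 were in WT_2, so its 9.10 without that library rests on no WT read and its size was not measured. The same holds for S100a9 without WT_3. The monocyte list had a camera adjusted p of 4.41e-06, and adjusted p = 0.651 with an estimated correlation. Treml4, a marker of patrolling monocytes in the same list chosen after its values were seen, followed the Xist pattern and not genotype, at 12.5 CPM in WT_2, 35.9 CPM in COP1KO_1 and 30.8 CPM in COP1KO_3 against 0.319, 0.520 and 0.690 CPM in WT_1, WT_3 and COP1KO_2. Of 14 border macrophage markers only Siglec1 was called by edgeR (also when adjusted over the list alone; DESeq2 and limma-voom called 1 and limma-voom with quality weights 3), at 7.85 ± 5.28 CPM in WT and 120 ± 32.6 CPM in COP1KO (log2 fold change 3.91, SE 0.46, adjusted p = 0.00615); the list was not called (camera adjusted p = 0.224, and adjusted p = 0.881 with an estimated correlation). Without WT_2 it was called (median 1.36, adjusted p = 0.00308), and without COP1KO_3 as well (0.30, adjusted p = 0.0386); 2 members were called without WT_2.

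In the endothelial list the called members went opposite ways. Flt1, a VEGF receptor gene, rose from 3.86 ± 1.08 to 110 ± 39.1 CPM (log2 fold change 4.82, SE 0.34, edgeR adjusted p = 0.000857), and Pecam1, an adhesion molecule of endothelium and leukocytes, fell from 37.4 ± 8.40 to 14.9 ± 4.28 CPM (log2 fold change -1.33, SE 0.26, adjusted p = 0.0365). The other 12 of the 14 tested were not called (2 higher and 1 lower when adjusted over the list alone, with DESeq2 and with quality weights; camera adjusted p = 0.550). Without WT_2 3 were called higher and 1 lower, and without COP1KO_2 2 higher. The Pecam1 call was lost without any 1 library except WT_2 (-1.53 to -1.14). Il7r fell among 6 tested T and NK cell markers (log2 fold change -1.34, SE 0.26; 1 higher and 1 lower when adjusted over the list alone and with DESeq2), and Cd79b among 4 B cell markers (log2 fold change -1.03, SE 0.19; 1 lower when adjusted over the list alone). Both genes were present in WT libraries, at means of 29.6 and 33 CPM, while most markers of these cells were too low to test, and neither list was called (camera adjusted p = 0.659 and 0.757). Both calls were lost without WT_1, WT_3, COP1KO_1 or COP1KO_3 (-1.58 to -1.22 for Il7r and -1.15 to -0.99 for Cd79b). The B cell list had a median of 0.30 and a mean of 1.24 but a downward camera direction; its median was 2.62 to 3.60 without any 1 WT library or COP1KO_2, where 6 members were tested. Without COP1KO_2, camera called the T and NK cell and the B cell lists higher (adjusted p = 0.000656 and 0.0179), and edgeR 1 and 2 of their 11 and 6 members tested there, with 1 called lower in each.

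No member was called by edgeR, over all genes tested or over the list alone, in the lists of dendritic cell (9 tested), neuron (15), astrocyte (14), oligodendrocyte lineage (15), mural cell and fibroblast (10) and choroid plexus markers (5). Unadjusted p lay under 0.05 for 4, 3, 1, 2, 1 and 3 of their members. DESeq2 called 1 oligodendrocyte lineage marker lower and no other, limma-voom none, and limma-voom with quality weights 2 dendritic cell markers lower, 2 neuron markers higher and 1 oligodendrocyte lineage marker each way. The members with the smallest p were Batf3 (log2 fold change -0.67, SE 0.19, adjusted p = 0.121), Syt1 (0.73, SE 0.22, adjusted p = 0.135), Gfap (1.71, SE 0.62, adjusted p = 0.227), Pdgfra (-1.70, SE 0.42, adjusted p = 0.0797), Col3a1 (-1.39, SE 0.51, adjusted p = 0.225) and Enpp2 (2.31, SE 0.72, adjusted p = 0.168). Batf3 and Pdgfra were called without WT_2 (-0.81 and -1.89) and Enpp2 without COP1KO_1 (2.78); 2 dendritic cell markers were called lower without WT_2, 2 choroid plexus markers higher without COP1KO_1, and 1 dendritic cell and 1 oligodendrocyte lineage marker higher without COP1KO_2. COP1KO_3 held the most Gfap and Enpp2, at 75.1 and 131 CPM, and its neuron markers summed to 568 CPM against 155 to 235 CPM in the other libraries. Without COP1KO_3 the log2 fold changes of Gfap and Enpp2 were smaller, at 0.55 and 1.19. The choroid plexus list was called by camera (adjusted p = 0.0129, and adjusted p = 0.651 with an estimated correlation); the choroid plexus call was lost without WT_2 (adjusted p = 0.0587). The other 5 lists had camera adjusted p of 0.659, 0.0629, 0.143, 0.123 and 0.759. Without COP1KO_2 the neuron, astrocyte and oligodendrocyte lineage lists were called higher (adjusted p = 0.0103, 0.00415 and 0.0103), and the neuron list also without COP1KO_1 (0.0187). The dendritic cell list turned positive without WT_1, COP1KO_2 or COP1KO_3 (medians 0.09, 0.30 and 0.27) and the mural list negative without WT_1 or COP1KO_3 (-0.02 and -0.49). With all libraries the dendritic cell list had a median of -0.17 and a mean of 0.23, and the mural list a median of 0.22 and a mean of 0.03 with a downward camera direction. No red blood cell gene had enough counts to be tested.

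Genes of proliferation did not pass the test. Of 26 cell cycle genes none was called by edgeR, none had an unadjusted p under 0.05, and Cdk1 had the smallest p (5.68 ± 1.19 and 3.38 ± 1.14 CPM, log2 fold change -0.75, SE 0.35, adjusted p = 0.32). DESeq2 and limma-voom called none either, with or without quality weights. Camera gave adjusted p = 0.224 for the list with all libraries and 0.00192 without COP1KO_3, where the median was -0.33. None of 22 glycolysis and hypoxia genes was called over all genes tested (edgeR; 4 had an unadjusted p under 0.05), and 1 was higher when adjusted over the list alone; DESeq2 called 3 higher, limma-voom 1 and limma-voom with quality weights 7, and edgeR 8 without WT_2, 3 with the sex-linked term and 1 with library size alone or 1 surrogate variable. Egln3, an oxygen sensor gene with the smallest p in that list, stood at 2.54 ± 2.5 CPM in WT and 18.1 ± 2.25 CPM in COP1KO (log2 fold change 2.79, SE 0.63, adjusted p = 0.0581), and was called without WT_2, at 4.07. The list was called by camera (adjusted p = 0.0165, and adjusted p = 0.791 with an estimated correlation), but not without WT_1, WT_3 or COP1KO_1 (adjusted p = 0.127, 0.224 and 0.117). None of 9 mitochondrially encoded genes was called or had an unadjusted p under 0.05 (edgeR), with mt-Atp6 at a log2 fold change of -0.95 (SE 0.66, adjusted p = 0.509); the list's median was 0.07 and its mean -0.10 (camera adjusted p = 0.994), and its median was -0.12 with library size alone, -0.23 without WT_2 and -0.09 without COP1KO_2. None of the 6 sex-linked genes was called between genotypes or had an unadjusted p under 0.05 (edgeR), with Tsix at 1.86 (SE 1.52, adjusted p = 0.589), a median of -0.85 and a mean of 0.05 (camera adjusted p = 0.659). DESeq2 and limma-voom, with or without quality weights, called no mitochondrial or sex-linked gene either. Mitochondrially encoded genes held only 0.0965% (WT_2) to 0.285% (WT_1) of counts, and mt-Atp6 had 4 to 17 reads per library. The result for these genes therefore covers only the reads that aligned uniquely. With 1 surrogate variable edgeR called 1 mitochondrial gene and 4 of the 6 sex-linked genes higher (medians 0.65 and 5.47), and with the sex-linked term 1 sex-linked gene higher (median 0.12). That variable was 0.389 in WT_2, 0.434 in COP1KO_1 and 0.350 in COP1KO_3, the Xist-high libraries. It was -0.514 in WT_1, -0.499 in WT_3 and -0.158 in COP1KO_2. It thus overlaps the sex-linked pattern, and the sex-linked calls of that fit cannot be read as changes with genotype. Tsix shares 32.6% of its exon bases with Xist on the opposite strand.

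**Figure D3:**
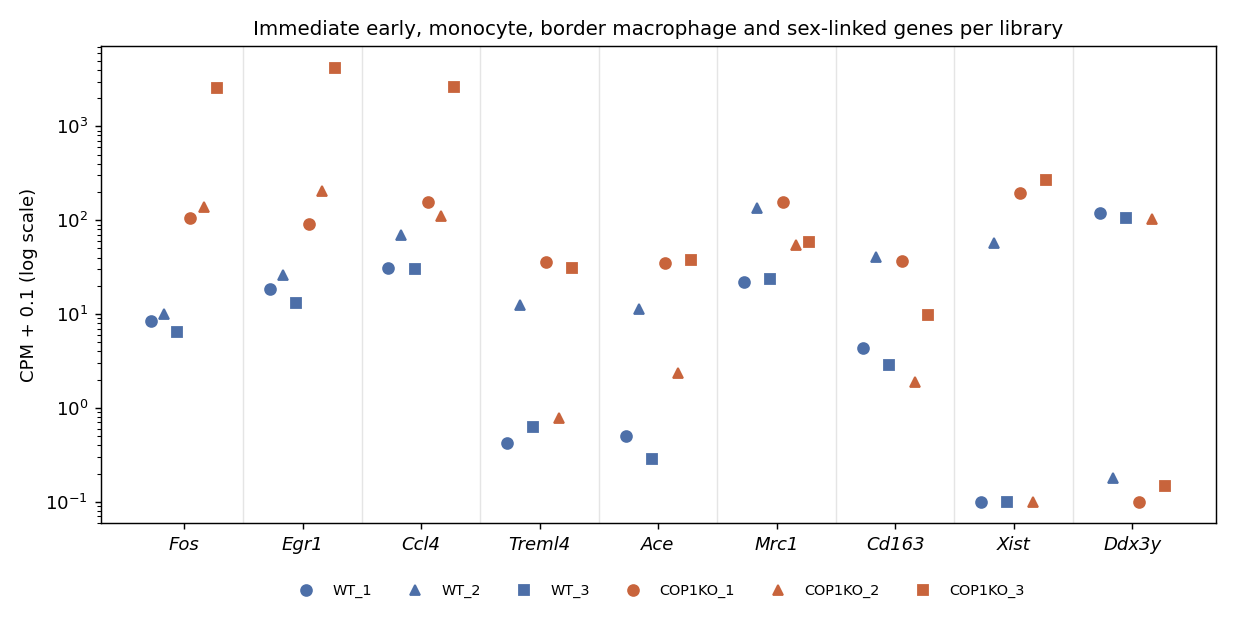
Points give CPM + 0.1 on a log scale for each library, with WT in blue and COP1KO in orange. Fos, Egr1 and Ccl4 were highest in COP1KO_3, while Treml4, Ace, Mrc1, Cd163, Xist and Ddx3y set WT_2 and COP1KO_1 apart from WT_1 and WT_3.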

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

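The term for the sex-linked pattern and the fit without COP1KO_3 and WT_2 were chosen after seeing the data. So was camera with DESeq2 size factors, upper quartile factors or 1 surrogate variable. The other settings were planned. Of 453 called genes (307 higher, 146 lower), none changed direction under another scaling or filter, with DESeq2, with limma-voom or with 1 surrogate variable. The count stayed within 1.5 times with DESeq2 size factors (436), upper quartile factors (471), library size alone (533), a mean of at least 1 CPM (475), no filter (633), limma-voom (338), no robust dispersion (441) and a minimum fold change of 1.2 (304). It left that range with DESeq2 (1227, 773 higher and 454 lower), limma-voom with sample quality weights (2198, 1318 higher and 880 lower), 1 surrogate variable (687, with 283 lower), a minimum fold change of 1.5 (165), the sex-linked term (766, 494 higher and 272 lower) and both COP1KO_3 and WT_2 left out (1646, 1008 higher and 638 lower). Genes called lower also moved by over 1.5 times with library size alone (240), with no filter (230) and with a minimum fold change of 1.2 (87). The cause was not tested in any of these, apart from the minimum fold change, which asks for larger changes by construction. Leaving out 1 library gave 88 to 1829 called genes, 63 to 1070 higher and 25 to 759 lower, the lowest without WT_1 and the highest without WT_2. Cop1 was not called in any setting, with log2 fold changes from -0.62 to -0.36 when 1 library was left out. Of the lists, 16 were called with camera's preset correlation, 15 to 22 when 1 library was left out, 17 with upper quartile factors, 17 with library size alone, 11 with 1 surrogate variable, 0 with an estimated correlation and 1 with fry. With 1 surrogate variable the lists of chemokines (adjusted p = 0.0507), MHC class II (0.241), Fc and phagocytic receptors (0.0550), lipid handling (0.0594), glycolysis and hypoxia (0.859) and choroid plexus markers (0.0652) lost their call, and that of mitochondrially encoded genes gained one, as higher (0.00735). The NADPH oxidase list gained a call with upper quartile factors (0.0488) and the neuron list with library size alone (0.0451). With the sex-linked term the glycolysis list lost its call (0.272) and the cell cycle list gained one, as lower (0.0497). Cebpd, not called, reversed without WT_2 (0.10), without COP1KO_1 (0.073) and without COP1KO_3 and WT_2 (0.068), and lay at -0.23 without COP1KO_2. Of the 54 named genes called, 0 lost the call with DESeq2, 12 with limma-voom, 15 without a filter, 36 without WT_1, 31 without WT_3, 23 without COP1KO_3, 22 without COP1KO_1, 8 without WT_2 and 7 without COP1KO_2. No paired analysis was possible because the labels give no replicate numbers. Depth limits genes of low count most in WT_1.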

Other observations

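The gene families in this paragraph and all tests in this part were chosen after the results were seen, apart from the splits for gene lists. For some tests the bounds were set down before the test was run. These were the monocyte tests of WT_2 by its position towards COP1KO_2 and COP1KO_1, the test of monocytes in COP1KO_1 and COP1KO_3 alone and the test of sex. The libraries and patterns in those tests still came from results already seen. Among replication-dependent histone genes 10 of 19 tested were called higher and none lower (edgeR, median log2 fold change 2.42). The libraries were made from polyA RNA, so these values cover only histone transcripts captured that way and may not follow total histone transcript levels. Hist1h1e, a linker histone gene, had a log2 fold change of 3.18 (SE 0.36, edgeR adjusted p = 0.00521) and Hist1h2bg of 3.02 (SE 0.38, adjusted p = 0.0073), while no cell cycle gene was called. Over 5 families, the camera adjusted p was 1.89e-11 for histones, and adjusted p = 0.035 with an estimated correlation. Of 5 Gimap genes, 3 fell: Gimap9, Gimap1 (-1.18, SE 0.15) and Gimap6 (-1.06, SE 0.15), with camera adjusted p = 1.26e-06, and adjusted p = 0.035 with an estimated correlation. Since these families were picked from the same data, their p-values are no independent evidence.

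Of 10 Ifi200 family genes, whose products sense nucleic acids, 7 rose, among them Ifi204 (log2 fold change 2.84, SE 0.29); camera gave adjusted p = 8.47e-07, and adjusted p = 0.142 with an estimated correlation. Of 11 genes matching TNF superfamily ligands, which include joined and antisense gene models, 5 rose, among them Tnfsf8 (2.48, SE 0.24) and Tnfsf13b (1.58, SE 0.19), with camera adjusted p = 8.47e-07, and adjusted p = 0.0594 with an estimated correlation. Of 8 Ms4a genes 3 rose, Ms4a4c, Ms4a6c and Ms4a6b (camera adjusted p = 0.000215, and adjusted p = 0.181 with an estimated correlation). Apart from genotype, 209 genes differed with the sex-linked pattern, 155 of them higher in the Xist-high libraries (edgeR with both terms), among them Treml4, Napsa, Ace, Lgals3 and Pltp. They included 5 of 14 monocyte markers, 4 of 14 border macrophage markers and 10 of 35 disease-associated microglial genes. The interaction of pattern and genotype was fitted in edgeR alone and cannot be judged. WT_2 was the only Xist-high library of WT, and COP1KO_2 the only COP1KO library without Xist reads.

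The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 453 genes and the highest other 45, so 1 of the 10 splits called as many; that other split follows the sex-linked pattern. For gene lists, 3 of the 10 splits called as many as the real one (16), the highest other calling 25, again the split by sex-linked pattern, which points to a structure of the samples beside genotype.

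All 21 tested immediate early genes had a fitted rise in COP1KO, and Fos reached 2577 CPM in COP1KO_3. Handling of COP1KO_3 alone is argued against as the whole cause, since 7 members of the list were called higher with COP1KO_3 left out, although none was with any 1 WT library left out. Handling that differed between the 2 groups stays open: 12 of 21 members had all 3 COP1KO libraries above all 3 WT libraries, which such handling and genotype both allow. How and when the cells were isolated is not given in the sources used here, so handling and genotype cannot be told apart for these genes. JUN is a substrate of COP1, and a biological origin may therefore be considered, but no test here separates it from handling.

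Blood cells mixed into the preparations are a further candidate explanation for genes higher in COP1KO. Monocytes in COP1KO_1 and COP1KO_3 alone are argued against as the whole cause, since they would leave COP1KO_2 near the WT level. Yet 89.2% of the 324 genes called higher without COP1KO_2 lay above all WT libraries in COP1KO_2. Chance gives 25% for genes chosen without regard to these WT values. These genes were chosen as low in WT, which raises that share by an amount that was not computed. Monocytes in all 3 COP1KO libraries are argued against as the whole cause as well. Over these 324 genes COP1KO_2 rose above WT by a median of 54.4% of the rise of COP1KO_1 (lower 95% bound 48.3%). Over the 16 monocyte markers the median was -6.16% and the upper quartile 29.5%, and the median was 7.07% when measured from WT_1 and WT_3 alone. Of the 16 markers, 11 were lower in COP1KO_2 than in WT_2. Ly6c2 and Treml4 were at 0.0862 and 0.690 CPM in COP1KO_2 against 1.02 and 35.9 CPM in COP1KO_1. Cd300e, outside the list, was at 0.0431 against 26.6 CPM. Itgal and Ms4a4c went the other way, at 170 and 22.2 CPM in COP1KO_2 against 265 and 44.8 CPM in COP1KO_1. Neutrophils are argued against as the origin of Cxcr2, since Camp, Ngp, Ltf, S100a8 and S100a9, among the most abundant neutrophil transcripts, together reached at most 0.549 of the Cxcr2 level in any COP1KO library. For those granule genes themselves traces of blood cells stay open: 5 of 5 ranked the COP1KO libraries as the hemoglobin gene Hbb-bs did, but Fos ranked them likewise, so the ranking cannot be told apart from that of COP1KO_3 standing out in general. Any gate or sort that would remove these cells is not given in the sources used here, and Cxcr2 expression by COP1KO microglia is a hypothesis that these data leave open.

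WT_2 lay between the groups over the genes called without it. Over the 1070 called higher its median position was 44.7% of the way from WT_1 and WT_3 to COP1KO, and over the 759 called lower 74.5%. Over the genes called with all libraries it was 6.12% for the 307 higher and 1.85% for the 146 lower. Those genes were called with WT_2 in the WT group, which favours a position near WT. The same position was -1.62% for WT_1 over 63 genes and -0.964% for WT_3 over 87, each set called higher without that library. WT_2 stayed in the WT group of those fits, which favours genes where the WT libraries lay close together. These values therefore cannot be set directly against the 44.7% of WT_2. Monocytes in WT_2 are argued against as the whole cause for the genes called lower. For the genes called higher, the tests with bounds set beforehand came out both ways. Over the genes called higher in COP1KO_2 against WT_1 and WT_3, WT_2 lay a median of 55.1% of the way to COP1KO_2. The lower 95% bound of that median was 50.3%, past the bound set beforehand against monocytes. Both libraries were measured from the same WT_1 and WT_3 that selected the genes. The position under no change in WT_2 was not computed, so this value alone cannot exclude monocytes. These genes come from a fit with 1 COP1KO library, whose spread was taken from WT_1 and WT_3, the closest pair. The bound needs COP1KO_2 to hold fewer monocyte transcripts than WT_2, which was so for 11 of the 16 listed markers; the list sum was higher in COP1KO_2 (233 against 118 CPM), but without Itgal lower (62.8 against 105 CPM). For the genes called lower, WT_2 stood a median of 36.5% below WT_1 and WT_3, and other cells can lower a gene at most by their share; the homeostatic microglial genes, which such a share would lower alike, were instead a median of 60.4% higher in WT_2 (lower quartile 12.7%), or 29.9% higher with library size alone (lower quartile -8.75%), where the genes called lower stood 48.6% below. The median rise of WT_2 over the 1070 genes was 43.6% of that of COP1KO_1, against 34.0% for Treml4, 31.3% for Ace and 23% for Hp. The rule set beforehand took a median at or above the lowest of these as a sign of monocytes, so this test came out for them. A high value also repeats the pattern itself, so it does not settle the question. Monocytes as a source of the rise in WT_2, as for Treml4, stay open. COP1KO RNA mixed into WT_2 is argued against by the 10 largest named rises, which reached at most 3.42% of their COP1KO mean there. Sex of the mice stays open: 37.9% of the genes from that same fit were higher still in both Xist-high COP1KO libraries, between the bounds set beforehand for and against it. A batch shared by WT_1 and WT_3 was not tested, since the labels give none, and may account for the position as well.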
